A study of Danio rerio with 8 samples.

How the data were processed

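Bulk RNA sequencing libraries of polyadenylated RNA from adult zebrafish hearts were compared, 4 from controls and 4 from fish with Hmga1a overexpression induced by tamoxifen, all 14 days after tamoxifen. Per the labels' protocols, ventricles were dissociated with collagenase and TrypLE, and the cells are labelled cardiomyocytes of cmlc2:dsred fish. How cells were selected for the libraries is not given in the sources used here, nor is the number of fish behind a library. Groups and sample numbers were taken from the sample titles.

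The authors deposited a table of estimated counts per gene for the 8 libraries, which are numbers of unique molecular identifiers corrected for identifiers used more than once. This was read from the values: with 4096 possible identifiers, the number of sequences of 6 nucleotides, the standard correction turns 100% of the 62181 non-zero values back into a whole number of identifiers (tolerance 0.01). The genome build danRer11 and edgeR are named in the submitters' processing notes. The aligner, the counting program, the gene annotation and the use of strand are not given in the sources used here. The table holds 21301 entries, of which 67 are spike-in RNAs, kept out of library sizes and tests, and 21234 are genes, 63 of them without a symbol. There are 29 mitochondrial entries, 13 with a gene name and 16 without. The correction grows steep near saturation, and 8 genes used over 90% of the identifiers in at least 1 library, so their counts are imprecise. They are 7 mitochondrial RNAs and the myoglobin gene mb, the latter in 2 libraries. The most abundant of these, a mitochondrial RNA without a symbol, used all 4096 identifiers in 5 libraries, where its count stands at a ceiling, and 4068 to 4094 in the other 3. Genes with near-identical copies, such as the titin pair ttn.1 and ttn.2, the myosin heavy chains, actins and histones, may share reads, and how these were counted is not known.

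The authors also deposited a comparison of 3 control and 3 overexpression libraries. Per the file headers it holds log2 fold changes, p-values and FDR values per gene from edgeR; which edgeR test and filter were used is not given in the sources used here. The count columns of the authors' deposited table equal controls 1, 3 and 4 and overexpression libraries 2, 3 and 4 in 100% of values (tolerance 1e-06), so control 2 and overexpression 1 were left out of it. The authors' deposited enrichment tables give, per the file headers, the number of genes per gene ontology term, the fold enrichment and a Benjamini-adjusted p-value. Gene names were used as the files give them. The reference tables of genes were not used for coordinates, since their build differs, and positions are not analysed here.

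Counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (minimum count 10), libraries were scaled by TMM, and groups were compared by the quasi-likelihood test (glmQLFit, robust) with no covariate and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Levels are TMM-scaled CPM with the SD over 4 libraries. The SE of a log2 fold change was derived from the coefficient and the F statistic of its test. The 27 gene lists, of which 24 had at least 3 tested members, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated one. Library measures were compared by exact permutation tests over the 70 assignments of 4 and 4 libraries, two-sided, for which the smallest p is 0.0286.

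The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are hmga1a, and the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 10 CPM, no overlap between the groups and a symbol (554 higher and 384 lower were eligible). Symbols that start with a clone or placeholder prefix listed in advance (such as si:, zgc:, LOC or an Ensembl ID) were passed over. XLOC was not among these prefixes, so XLOC_014477 was eligible, as was the eGFP entry. They also are up to 4 members of each list with the smallest p past the threshold, or the 2 most abundant where no member passed, the reporters, and the 5 genes with the largest share of counts. Members of lists named beside these, among them myh7, tnnt2a, flna, ryr2b, jund, cebpd, nr4a1, atf3, btg2, cox4i2, ppargc1b, lpl, slc16a3, slc2a1b, krt18a.1 and ctss2.1, were chosen after their values were seen.

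The test was tried on simulated counts with a dispersion of 0.1, made from the means and library sizes of these libraries. Of 2515 genes tested, 170 of the 200 simulated as changed passed the filter. For this comparison 31.5% of 2-fold and 97.5% of 4-fold changes were recovered, 100% with the right sign, beside 4 false calls (3.60% of calls). A simulated raised list passed camera (adjusted p = 2.2e-35) and 0 other lists did. Genes were simulated as independent of each other, with few changed and with rises and falls in equal number. These rates therefore do not carry over to lists of correlated genes or to data in which most tested genes change.

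Total counts per library ranged from 49598 to 572295, and control 2 had the lowest total and 3318 detected genes, against 7578 to 9035 in the other controls and 7706 to 8946 with overexpression. To look for a library deposited more than once, pairs of libraries of a group were compared by chi-square. No pair was within sampling noise (chi-square over degrees of freedom from 2.66 to 6.80), which says nothing of whether libraries came from separate fish. Alternatives were DESeq2 size factors, library totals alone, mitochondrially encoded genes removed, no filter, a filter of at least 5 CPM in at least 4 libraries, and DESeq2 1.42.0. Others were limma-voom, edgeR's exact test, the sample number as a replicate block, libraries thinned to the smallest, and each library left out. The 5 CPM filter kept 6175 genes against 2501 in the main test, so it was looser and added genes of low count. Alternatives chosen after seeing the data were the authors' 6 libraries, observed identifiers in place of corrected counts, the 20 genes removed that used over 50% of the identifiers in any library, and libraries scaled on contractile genes.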

Results

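Gene expression was measured in adult zebrafish heart cells that the labels name cardiomyocytes, from dissociated ventricles. The fish carried a cmlc2:dsred reporter, in which a cardiomyocyte promoter drives a red fluorescent protein. There were 4 control libraries and 4 libraries with Hmga1a overexpression, all taken 14 days after tamoxifen. Hmga1a is an AT-hook protein of chromatin, and the comparison asks what its overexpression changes in uninjured hearts. Total corrected transcript counts per library were 352807, 49598, 238142 and 344241 in controls 1 to 4, and 363940, 544878, 302157 and 572295 in overexpression libraries 1 to 4. The labels do not say whether each library came from its own fish, so p-values measure the spread between these libraries, part of which may be technical. The 2 groups' totals did not differ beyond the spread between libraries (p = 0.114, exact permutation test, two-sided, n = 4 per group; adjusted p = 0.191 over 10 library measures).

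The transcript of the target gene, hmga1a (LL0000012165 in the count table), was at 127.4, 30.2, 75.01 and 58.9 CPM (counts scaled to a common library total by TMM) in controls 1 to 4 and at 80.7, 132.8, 128.6 and 130.6 CPM in overexpression libraries 1 to 4. These levels rest on few corrected counts, 45.24, 1, 14.02 and 16.03 in controls 1 to 4. The overexpression libraries 1 to 4 held 34.14, 79.76, 42.21 and 78.74. The means were 72.9 ± 40.8 CPM and 118.2 ± 25.1 CPM (SD, n = 4), a log2 fold change of 0.47 ± 0.30 (SE) that did not pass edgeR's quasi-likelihood test (adjusted p = 0.177). It passed without control 1 (0.85, adjusted p = 0.0444), with library totals alone (0.80, 0.0486) and with a stricter filter (0.72, 0.0492), and was -0.69 when libraries were scaled on contractile genes. Adjusted p ranged from 0.0444 to 0.558 over the alternatives. In the authors' deposited table, which uses 6 of the libraries, the hmga1a log2 fold change is 0.84 with an adjusted p of 0.0227. The same 6 libraries in the test used here gave 0.58 and did not pass (adjusted p = 0.0852, edgeR). The labels do not describe the 3′ end of the transgene, so these counts may leave out part of its transcript and check the overexpression label only in part. The dsRED reporter rose from 583.9 ± 38.01 CPM to 3050 ± 761 CPM (log2 fold change 2.36 ± 0.17, adjusted p = 2.1e-12, edgeR), higher in every overexpression library than in every control. An entry named eGFP, whose construct the labels do not describe, also rose from 128.7 ± 85.1 CPM to 608.6 ± 60.9 CPM (2.60 ± 0.26, adjusted p = 1.2e-09, edgeR). Relative to dsRED, eGFP did not differ between the groups beyond the spread, at 22.8% ± 16.2 of dsRED counts in controls and 20.9% ± 5.58 with overexpression (p = 0.914, exact permutation test, n = 4 per group; adjusted p = 0.914). hmga1a counts were 12.2% ± 6.14 of dsRED counts in controls and 4.00% ± 1.16 with overexpression (p = 0.0571, exact permutation test, n = 4 per group; adjusted p = 0.114).

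**Figure D1:**
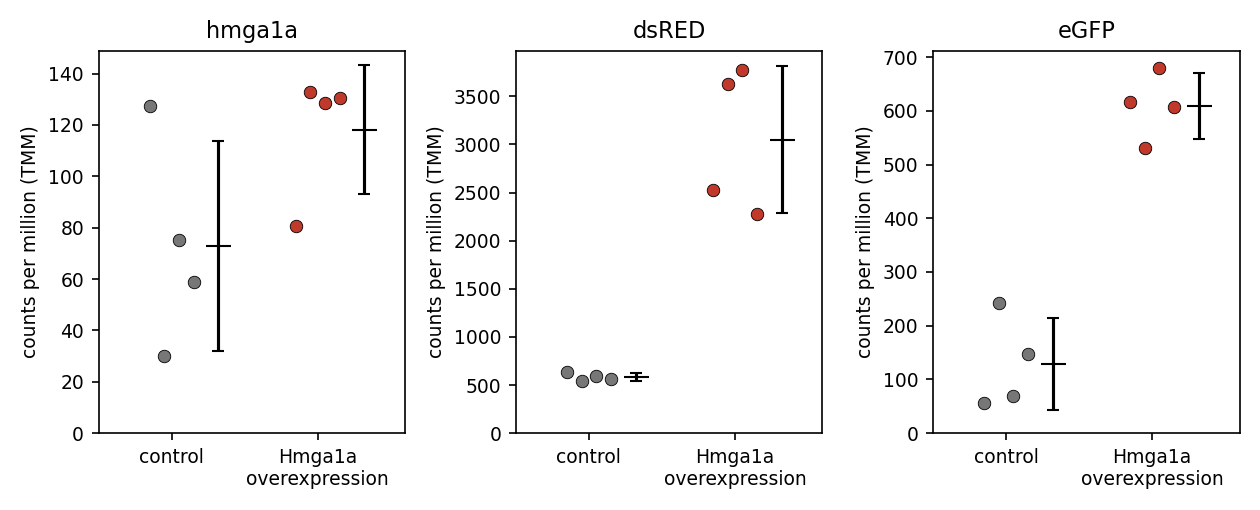
TMM-scaled CPM of hmga1a, dsRED and eGFP in each library, with points for the 4 control and 4 overexpression libraries and a bar for the mean ± SD of each group. The groups overlap for hmga1a, at 72.9 and 118.2 CPM on average, and do not overlap for the reporters.

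Mitochondrial RNA made up 56.1% ± 9.35 of counts in controls and 31.7% ± 2.98 with overexpression (SD, n = 4), a difference of -24.4 percentage points. Every overexpression library lay below every control (p = 0.0286, exact permutation test, two-sided, the smallest p that 4 against 4 libraries can give; adjusted p = 0.0953 over the 10 library measures). The most abundant mitochondrial RNA, which has no gene symbol, used all 4096 possible identifiers in 5 libraries (controls 1, 3 and 4 and overexpression 2 and 4), where its count stands at a ceiling. It used 4068 to 4094 in the other 3, where its count is imprecise, so its share is not compared. Without it the mitochondrial share was 41.1% ± 5.66 against 24.3% ± 2.03, a difference of -16.8 percentage points (p = 0.0286, exact permutation test, n = 4 per group; adjusted p = 0.0953). The others among the 5 with the largest share of counts, each over 90% of the identifiers in 3 to 7 libraries and so imprecise, were mt.co1 (5.66% and 3.98%), mt.co2 (4.84% and 3.57%), mt.atp6 (4.60% and 3.33%) and COX3 (2.79% and 2.105%), all mitochondrially encoded. Counts outside the mitochondrial genome had library means of 117200 in controls and 302100 with overexpression (p = 0.0286, exact permutation test, n = 4 per group; adjusted p = 0.0953). Without any single overexpression library the difference in mitochondrial share lay between -25.5 and -23.2 points, and between -17.8 and -16.3 points without the most abundant RNA, each with p = 0.0571 in the exact permutation test over 35 assignments. Without any single control it lay between -28.1 and -20.5 points, and between -19.5 and -15.5 without that RNA, each with p = 0.0286 in the same exact test.

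**Figure D2:**
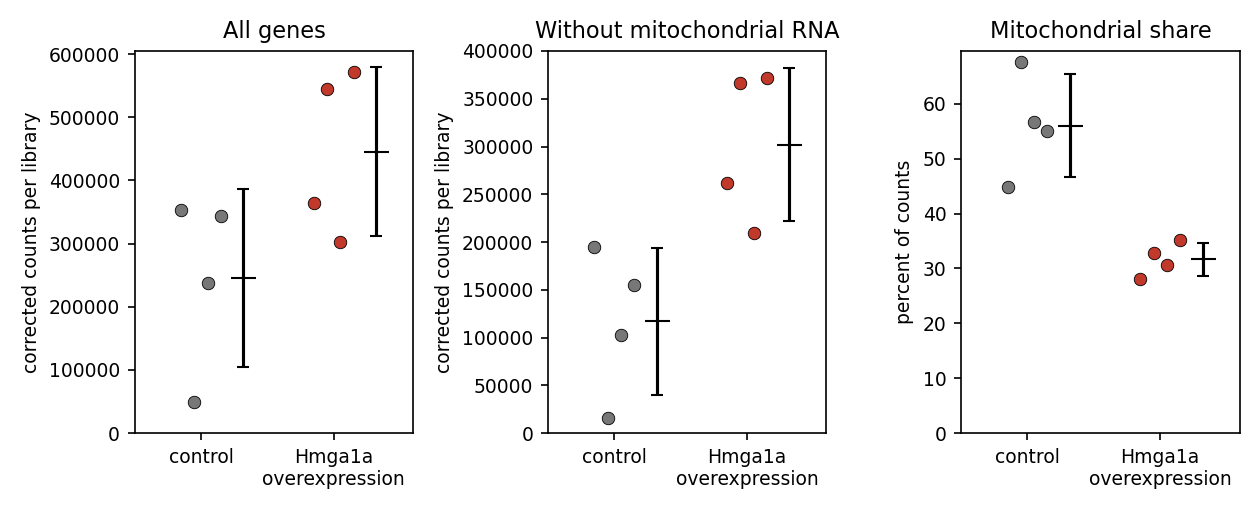
Corrected transcript counts per library, for all genes and without mitochondrial RNA, and the mitochondrial share of counts in percent. Points are the 4 control and 4 overexpression libraries and bars the mean ± SD. The mitochondrial share, which includes an RNA whose count stands at a ceiling in 5 libraries, averages 56.1% in controls and 31.7% with overexpression, with no overlap.

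Of 2501 genes tested, 760 rose and 730 fell with Hmga1a overexpression (adjusted p under 0.05, edgeR's quasi-likelihood test), and 551 of the risers and 583 of the fallers changed at least 2-fold. The split depends on the scaling: 51.0% of the changed genes were higher with TMM, 66.8% with library totals alone, and 6.58% (102 higher and 1448 lower) with libraries scaled on contractile genes, an alternative chosen after seeing the data. In 1084 genes (43.3%) the 4 overexpression libraries lay all above or all below the 4 controls, against 2.86% by chance. The largest rises among the named genes were those of homer2, a scaffold protein of the postsynapse and of muscle (log2 fold change 3.47 ± 0.66), of dusp22b, a dual-specificity phosphatase (3.12 ± 0.66) and pgam2, the muscle phosphoglycerate mutase of glycolysis (2.90 ± 0.57). Next were dmac2l (2.86 ± 0.59), dhrs4, a dehydrogenase/reductase (2.71 ± 0.53), and glrx5, a mitochondrial glutaredoxin of iron-sulfur cluster assembly (33.7 ± 17.9 to 174.6 ± 34.4 CPM). They were followed by ube2ka (2.65 ± 0.52), srd5a2a (2.64 ± 0.42), ASS1, argininosuccinate synthase (74.9 ± 52.0 to 337.5 ± 5.36 CPM), the eGFP entry, ndufb11 of respiratory complex I (2.54 ± 0.51) and cdc42ep3 (2.51 ± 0.49). Control levels were near the floor for homer2 (2.55 ± 3.47 CPM), dusp22b (4.10 ± 5.27), dmac2l (4.60 ± 3.19), dhrs4 (5.51 ± 4.51) and ube2ka (7.07 ± 6.82). Each of these genes was at 0 in control 2, so the size of its rise is imprecise. The largest fall was that of myh6, an atrial myosin heavy chain (185.2 ± 135.3 to 11.8 ± 5.18 CPM, -4.00 ± 0.43). The next genes included the cytokine il6 (-3.77 ± 0.50) and tnip2 (-3.49 ± 0.40). They also included the NF-kB subunit gene nfkb2 (-3.39 ± 0.34), the NF-kB feedback inhibitor tnfaip3 (748.8 ± 256.5 to 83.1 ± 21.2 CPM, -3.28 ± 0.22) and the chemokine ccl34b.4 (-3.17 ± 0.24). The others were the complement gene c6 (-3.50 ± 0.49), wasb, an actin regulator of blood cells (-3.44 ± 0.45), a locus without a gene name, XLOC_014477 (-3.43 ± 0.50), the transcription factor ets1 (-3.25 ± 0.41), tagapa (-3.25 ± 0.28) and HACD4 (-3.11 ± 0.49). All 24 genes had adjusted p of at most 0.000116 in edgeR's quasi-likelihood test. In the same libraries markers of endothelial cells, fibroblasts and leukocytes had medians of -1.85, -1.90 and -1.92, and the mitochondrial share without the most abundant RNA was 41.1% in controls and 24.3% with overexpression.

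The authors' deposited table, an edgeR comparison of 3 control and 3 overexpression libraries over 7998 genes, marks 1280 genes as up and 1203 as down, which are those with an unadjusted p under 0.05 and a log2 fold change beyond 1 in either direction. The highest adjusted p among the genes it marks is 0.138. Of the 2501 genes tested here, all of which the table holds, 1256 were called in both at an adjusted p under 0.05, each with the same sign, 234 only here and 123 only in the authors' deposited table. Among gene ontology terms of the raised genes, the authors' deposited table gives mitochondrion (232 genes, 4.83-fold enriched, adjusted p = 1.3e-95), ribosome (55 genes, 6.28-fold), tricarboxylic acid cycle (16 genes, 10.3-fold) and glycolytic process (15 genes, 7.41-fold). For the lowered genes, the authors' deposited table gives cell migration (32 genes, 3.85-fold enriched, adjusted p = 3.3e-07), angiogenesis (31 genes, 3.41-fold) and immune response (37 genes, 2.71-fold). The background given in the authors' deposited table is 18868 genes for mitochondrion and 18397 for cell migration, beside the 7998 genes of its comparison.

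Most tested nuclear genes of energy metabolism rose. Of 52 tested nuclear genes of oxidative phosphorylation, 51 rose and 0 fell, with a median log2 fold change of 1.61. Among them were cox4i1l of complex IV (551.2 ± 74.4 to 2328 ± 190 CPM, 2.13 ± 0.15), cox7a1 (2.17 ± 0.16), atp5po of ATP synthase (2.01 ± 0.15) and cox6b2 (1.96 ± 0.15), while cox4i2 was at 0.26 ± 0.48 (adjusted p = 0.655, edgeR). Of 14 genes of the tricarboxylic acid cycle, 13 rose and 0 fell, with a median of 1.51. They included idh2 (992 ± 112 to 3093 ± 235 CPM), mdh1ab (2.28 ± 0.21), mdh1aa (1.52 ± 0.14) and pdhb (1.5 ± 0.17). Of 20 genes of fatty acid oxidation, 16 rose and 2 fell, with a median of 1.56. The genes etfa (2.04 ± 0.27), hadhaa (1.75 ± 0.24), hadhb (1.87 ± 0.26) and acsl1b (1.35 ± 0.20) rose. The coactivator gene ppargc1b (-1.14 ± 0.25) and the lipoprotein lipase gene lpl (-1.25 ± 0.42) fell. Of 22 genes of glycolysis, 15 rose and 2 fell, with a median of 0.85. Muscle enolase eno3 (748.5 ± 184.7 to 2855 ± 351 CPM), tpi1b (1.66 ± 0.15), aldoab (1.46 ± 0.16) and pgk1 (1.26 ± 0.15) rose, while the membrane transporter genes slc16a3 (-1.22 ± 0.40) and slc2a1b (-0.83 ± 0.30) fell. Both falls lost their call with library totals alone and with no filter, where 16 glycolysis genes were higher and 0 lower. In contrast, 11 of 12 mitochondrially encoded genes fell and 0 rose, with a median of -0.95. The median was -0.49 with library totals alone, with 10 lower, and -1.98 with scaling on contractile genes, with 12 lower. The genes that fell included mt.nd5 (4223 ± 878 to 2016 ± 183 CPM, -1.09 ± 0.15), mt.nd1 (-0.96 ± 0.15), mt.nd3 (-0.91 ± 0.16) and mt.cyb (-0.98 ± 0.17). The mean log2 CPM of nuclear respiratory genes minus that of mitochondrially encoded genes, taken within each library, was -5.37 ± 0.34 in controls and -3.01 ± 0.15 with overexpression (p = 0.0286, exact permutation test, n = 4 per group). That p is unadjusted and the smallest possible. The measure was chosen after the lists were seen to move in opposite directions, so it adds no separate support.

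Each of these 5 lists passed limma's camera test against the other genes. Adjusted p was 6.9e-27 for oxidative phosphorylation, 1.1e-07 for the tricarboxylic acid cycle, 0.00016 for fatty acid oxidation, 0.00084 for glycolysis and 0.00016 for mitochondrially encoded genes. Each lost that call with an estimated correlation in place of the preset 0.01. Adjusted p was then 0.272 for oxidative phosphorylation, the tricarboxylic acid cycle and glycolysis, 0.285 for fatty acid oxidation and 0.328 for mitochondrially encoded genes. Adjusted over the list alone, 51 genes of oxidative phosphorylation, 13 of the tricarboxylic acid cycle, 16 of fatty acid oxidation and 16 of glycolysis rose. In the same count 2 genes of fatty acid oxidation, 2 of glycolysis and all 12 mitochondrially encoded genes fell. With the genes removed that used over 50% of the identifiers in any library, an alternative chosen after seeing the data, 4 of the 12 mitochondrially encoded genes were tested. Their median was -0.96 and the list's adjusted p in camera 0.0774. When libraries were scaled on contractile genes, the median of all genes shifted by -1.12 on the log2 scale. Fewer genes then passed as higher, 22 of 52 for oxidative phosphorylation (median 0.49), 5 of 14 for the tricarboxylic acid cycle (0.43) and 6 of 20, with 2 lower, for fatty acid oxidation (0.44). Glycolysis went to a median of -0.27, with 3 genes higher and 7 lower. Under that scaling aldoab (0.36), pgk1 (0.16), pdhb (0.43) and acsl1b (0.22) no longer passed, and with libraries thinned to the smallest hadhaa (0.65) did not. Markers of endothelial cells, fibroblasts and leukocytes fell in the same libraries (medians of -1.85, -1.90 and -1.92).

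Most tested genes of the cardiomyocyte contractile apparatus rose. Of 20 tested, 15 rose and 3 fell, with a median log2 fold change of 1.18. The remaining 2, tpm1 (-0.24 ± 0.31, adjusted p = 0.519) and nexn (-0.04 ± 0.40, adjusted p = 0.949), did not pass edgeR's test. The troponin gene tnnc1a rose from 1305 ± 141 to 4949 ± 305 CPM (1.94 ± 0.14) and the cardiac actin gene actc1a from 1464 ± 115 to 4858 ± 1134 CPM (1.73 ± 0.16). The genes tnnt2a (1.25 ± 0.16) and myh7 (2.04 ± 0.21) rose as well. The titin genes ttn.2 and ttn.1, which encode the giant elastic protein of the sarcomere, fell from 2404 ± 525 to 612.6 ± 86.1 CPM (-2.01 ± 0.15) and from 1039 ± 328 to 320.2 ± 61.8 CPM (-1.77 ± 0.18), and myh6 was the third that fell. Counts of the titin pair and of the myosin heavy chain genes are uncertain as to which copy they belong to, since near-identical copies can share reads. Of 8 genes of calcium handling and ion channels, 5 rose and 1 fell, with a median of 0.998. The calcium pump gene atp2a2a (1.2 ± 0.14), fkbp1b (2.17 ± 0.26), the calsequestrin gene casq2 (1.69 ± 0.20) and atp1b1a (0.79 ± 0.13) rose, and the ryanodine receptor gene ryr2b fell (-0.90 ± 0.25). The fall of ryr2b lost its call with library totals alone, where 5 genes of this list were higher and 0 lower. Of 15 genes of embryonic or border-zone cardiomyocytes, 8 rose and 1, flna (-1.39 ± 0.32), fell, with a median of 0.93. The natriuretic peptide genes nppa (347.1 ± 76.5 to 882.8 ± 57.0 CPM) and nppb (396.7 ± 161.5 to 791.8 ± 58.7 CPM), desmin (desma, 1.65 ± 0.19) and the transcription factor nkx2.5 (1.48 ± 0.26) rose.

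The 3 cardiomyocyte lists passed camera (adjusted p = 0.0013, 0.024 and 0.011, in that order) and lost the call with an estimated correlation (adjusted p = 0.285, 0.272 and 0.328). Adjusted over the list alone, 15 contractile genes rose and 3 fell, 5 calcium genes rose and 1 fell, and 9 embryonic or border-zone genes rose and 1 fell. With the genes removed that used over 50% of the identifiers in any library, 15 contractile genes were tested, with a median of 1.18 as before and an adjusted p of 0.0584. The calcium list also lost its call without control 4 (adjusted p = 0.115) and without each overexpression library (adjusted p from 0.0559 to 0.0947). With libraries scaled on the contractile genes the calcium list had 1 gene higher and 3 lower (median -0.10) and the embryonic list 1 higher and 4 lower (-0.18). Under that scaling fkbp1b (1.07) and desma (0.51) still passed as higher, while atp2a2a (0.11), casq2 (0.54), nppa (0.30), nppb (0.05) and nkx2.5 (0.34) no longer passed and atp1b1a was at -0.30. With thinned libraries fkbp1b (0.81), atp1b1a (0.31), nppa (0.41) and nppb (0.299) did not pass. In the same libraries dsRED, driven by a cardiomyocyte promoter, rose 5.14-fold, and markers of endothelial cells, fibroblasts and leukocytes had medians of -1.85, -1.90 and -1.92.

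**Figure D3:**
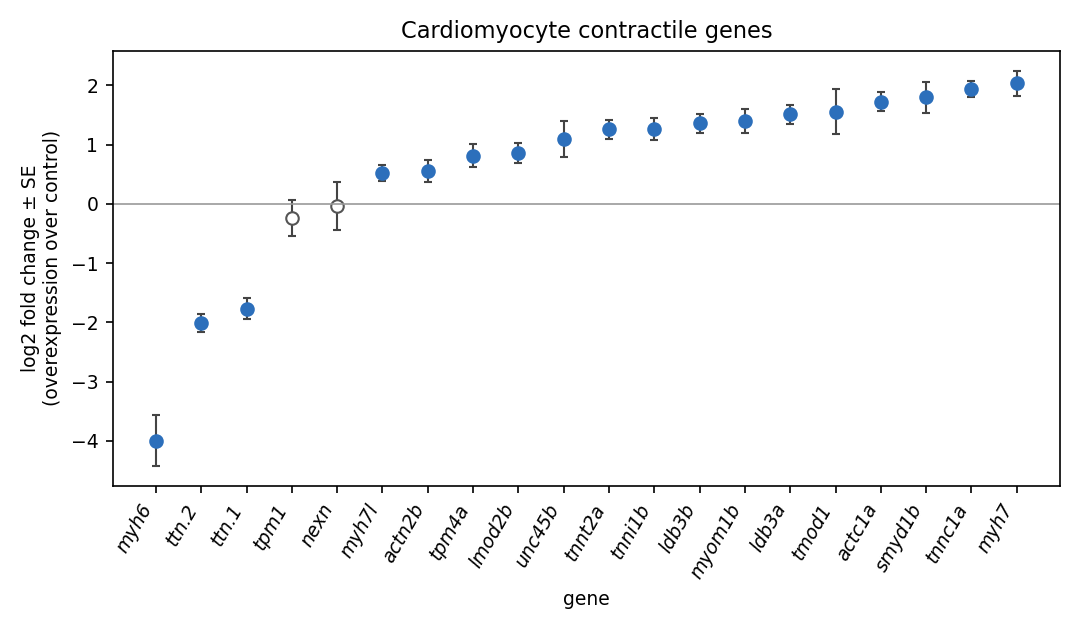
Log2 fold change (overexpression over control) ± SE of each tested contractile gene, filled where adjusted p is under 0.05 in edgeR's test. myh6 (-4.00), ttn.2 (-2.01) and ttn.1 (-1.77) fell while 15 genes rose.

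Most tested genes induced early by stimuli and by tissue dissociation fell. Of 20 tested immediate early genes, 15 fell and 2 rose, with a median log2 fold change of -1.81 (camera adjusted p = 9.6e-07, and adjusted p = 0.285 with an estimated correlation; 15 lower and 2 higher adjusted over the list alone). junba fell from 1499 ± 89 to 385.1 ± 39.1 CPM (-1.96 ± 0.14) and cebpb from 757.9 ± 219.2 to 171.5 ± 11.2 CPM (-2.23 ± 0.18). The gene junbb (-2.4 ± 0.25) and the NF-kB inhibitor nfkbiaa (-2.68 ± 0.29) fell as well. jund (0.57 ± 0.16) and cebpd (0.75 ± 0.23) rose, and nr4a1 (-0.18 ± 0.17), atf3 (-0.13 ± 0.17) and btg2 (-0.07 ± 0.16) did not pass edgeR's test (adjusted p = 0.386, 0.530 and 0.725). Heat shock genes went both ways, with 6 of 20 higher and 9 lower (camera adjusted p = 0.221; the same counts adjusted over the list alone), and their median was -0.08. It turned to 0.32 with scaling on library totals alone, to 0.033 with the 5 CPM filter and to 0.174 over 19 genes with hsp70l removed, which used over 50% of the identifiers. The cytosolic chaperone genes hsp90aa1.2 (5868 ± 1053 to 863.6 ± 66.9 CPM, -2.77 ± 0.15), hsp70l (7063 ± 1306 to 1649 ± 288 CPM, -2.11 ± 0.16) and hspa4a (-1.63 ± 0.16) fell. The small heat shock gene hspb6 rose (424.7 ± 123.0 to 1419 ± 129 CPM, 1.85 ± 0.17). Of 13 genes of the integrated stress and unfolded protein responses, 7 fell, among them ddit3 (-1.35 ± 0.17), xbp1 (-1.56 ± 0.23) and herpud1 (-2.17 ± 0.36), and 1, mthfd2 (1.91 ± 0.41), rose, with the same counts adjusted over the list alone. The list did not pass camera (adjusted p = 0.0594), but did without control 4 (adjusted p = 0.0311). With library totals alone 3 of its genes were lower and 2 higher (median -0.30), and with scaling on contractile genes 12 were lower and 0 higher (-1.79). Under contractile scaling 0 immediate early genes were higher and 19 lower, and 1 heat shock gene was higher and 14 lower, against 8 higher and 5 lower with library totals alone. In the same libraries markers of endothelial cells, fibroblasts and leukocytes had medians of -1.85, -1.90 and -1.92, and the mitochondrial share without the most abundant RNA was 41.1% in controls and 24.3% with overexpression.

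Of 54 genes of cytosolic ribosomal proteins, 45 rose and 0 fell, with a median log2 fold change of 0.58. The median turned to -0.50, with 33 lower, when libraries were scaled on contractile genes. rps3a (0.94 ± 0.14), rpl17 (0.94 ± 0.14), rpl14 (0.80 ± 0.14) and rpl32 (0.78 ± 0.13) were among those that rose. The list passed camera (adjusted p = 4.1e-07), and it lost the call with an estimated correlation (adjusted p = 0.285). Adjusted over the list alone, 45 rose. In the same libraries markers of endothelial cells, fibroblasts and leukocytes had medians of -1.85, -1.90 and -1.92, and the mitochondrial share of counts without the most abundant RNA was 41.1% in controls and 24.3% with overexpression. With all libraries thinned to the smallest, 2 ribosomal protein genes rose and 2 fell of 47 tested. Only 505 genes were then tested in all, and log2 fold changes of genes tested in both fits shifted by a median of -0.605. Of 11 genes of ribosome biogenesis, 1, mycb (-0.69 ± 0.19), fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.986; median -0.19, mean 0.03). The median was 0.167 with library totals alone. With contractile scaling 6 were lower. The call of mycb was lost with library totals alone (-0.31), no filter (-0.43), the 5 CPM filter (-0.42) and DESeq2 (-0.51). Of 5 tested HMG relatives, hmgb3b (1.42 ± 0.39) and hmgn3 (1.198 ± 0.38) rose, also adjusted over the list alone. Each missed the threshold without control 1 (0.97 and 1.08, adjusted p = 0.0575 and 0.0506, edgeR). The list did not pass camera (adjusted p = 0.412), and its median of 0.48 was -0.64 with scaling on contractile genes, with 0 higher and 1 lower, against 4 higher with library totals alone.

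Growth factor and chromatin genes were thinly measured. Of 7 tested targets of the ERK pathway, phlda1 rose (2.32 ± 0.44) and spry4 (-0.94 ± 0.19), mycb and epha2a (-1.14 ± 0.46) fell, also adjusted over the list alone (camera adjusted p = 0.647). The list had 2 higher and 0 lower with library totals alone, and 1 higher and 5 lower with contractile scaling. The gene epha2a missed the threshold when any of 6 libraries was left out, all but control 4 and overexpression 3 (adjusted p from 0.0504 to 0.148). Of 3 tested ErbB and growth factor signalling genes, the receptor gene erbb2 (-1.44 ± 0.43) and the ligand gene hbegfa (-0.998 ± 0.41) fell, also adjusted over the list alone (camera adjusted p = 0.586). The gene hbegfa missed the threshold without control 3 (-0.42, adjusted p = 0.426) and without overexpression 1, 3 or 4 (adjusted p = 0.0753, 0.0588 and 0.135). Both epha2a and hbegfa also missed it with library totals alone, no filter, the 5 CPM filter and DESeq2. The call of spry4 was lost with library totals alone (-0.55), and that of erbb2 with no filter (-1.202) and in DESeq2 (-1.27). Of 6 polycomb and trithorax genes, the histone demethylase gene kdm6ba (699.8 ± 70.7 to 238.2 ± 37.3 CPM, -1.56 ± 0.17), kmt2bb (-1.76 ± 0.30) and kmt2ca (-1.49 ± 0.38) fell and 0 rose, also adjusted over the list alone, without a call for the list (camera adjusted p = 0.134). Its median of -1.16 was 0.405 in DESeq2, where 13 members were tested, and 0.272 without a filter, where 22 were. Of 16 genes of developmental transcription factor families, 6 rose and 5 fell, also adjusted over the list alone. The genes nkx2.5 and tbx5a (1.46 ± 0.37), regulators of heart development, rose, and foxo1a (-2.02 ± 0.27) and sox9b (-2.88 ± 0.44) fell (camera adjusted p = 0.957; median 0.20 and mean -0.10). The median was -0.919 with scaling on contractile genes, with 0 higher and 8 lower. In the same libraries markers of endothelial cells, fibroblasts and leukocytes had medians of -1.85, -1.90 and -1.92, and the mitochondrial share without the most abundant RNA was 41.1% in controls and 24.3% with overexpression. Cell cycle genes were near the limit of detection. Of 45 in the table, 1 passed the filter, pcna, at -0.43 ± 0.31 (adjusted p = 0.240, edgeR). The 45 genes together held 96 counts in controls and 193 with overexpression, or 246.7 ± 87.9 and 164.3 ± 29.5 CPM of non-mitochondrial counts (p = 0.0857, exact permutation test, n = 4 per group). The adjusted p was 0.171 over 3 lists summed after their low counts were seen, and a difference in proliferation genes was not detectable at this depth.

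Most tested markers of endothelial cells, fibroblasts and leukocytes fell. All 10 tested endothelial and endocardial markers fell, with a median log2 fold change of -1.85. They included aqp8a.1 (1241 ± 145 to 247.3 ± 64.3 CPM, -2.31 ± 0.17), flt1 (-2.90 ± 0.36), she (-1.94 ± 0.36) and kdr (-1.74 ± 0.38). Of 9 fibroblast and epicardial markers, 8 fell and 1, anxa2a (1.38 ± 0.14), rose, with a median of -1.90. The genes fn1b (680.3 ± 277.4 to 111.3 ± 7.61 CPM), krt8 (2166 ± 337 to 762.7 ± 92.9 CPM) and rbp4 (-2.15 ± 0.21) were among those that fell. Of 13 leukocyte markers, 12 fell and 0 rose, with a median of -1.92. They included cd74a (4036 ± 924 to 1274 ± 180 CPM) and cd74b (1077 ± 341 to 413.8 ± 40.4 CPM), with marco (-1.95 ± 0.24) and wasb. Within lists the members differed, from krt18a.1 (-1.14 ± 0.17) to c6 (-3.50 ± 0.49) among the fibroblast markers that fell and from ctss2.1 (-0.60 ± 0.20) to wasb (-3.44 ± 0.45) among the leukocyte markers (p = 0.0286 for each list, exact permutation test of unequal change over libraries). All 3 tested thrombocyte markers fell: fn1b, plek (-1.28 ± 0.36) and fli1a (-1.50 ± 0.46), which lost its call without control 1 (-1.12, adjusted p = 0.108). In DESeq2 plek (-1.07) and fli1a (-1.19) did not pass. All 3 tested genes of the extracellular matrix list fell, fn1b, col1a1b (-2.48 ± 0.30) and col4a1 (-2.75 ± 0.35). These lists passed camera (adjusted p = 0.00038, 8e-05, 1.2e-05, 0.033 and 0.00067, in the order given). They lost the call with an estimated correlation (adjusted p = 0.272 for all but thrombocytes, 0.328). The counts adjusted over the list alone were equal to those given. The thrombocyte list also lost its call without overexpression 1 or 2 (adjusted p = 0.0633 and 0.06104), with library totals alone (0.0504) and over the 6 libraries of the authors (0.0586). fn1b stands on the fibroblast, thrombocyte and matrix lists, fli1a on the endothelial and thrombocyte lists and col1a1b on the fibroblast and matrix lists. Of the tested thrombocyte markers, plek alone is on no other list, so the fall of that list largely repeats the others. Alongside these falls dsRED rose 5.14-fold, contractile genes had a median of 1.18 and immediate early genes one of -1.81. The mitochondrial share without the most abundant RNA was 41.1% in controls and 24.3% with overexpression.

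Smooth muscle markers went both ways. Of 4 tested, acta2 (1.54 ± 0.27), tagln (1.36 ± 0.23, also on the list of embryonic cardiomyocyte genes) and smtnb (1.46 ± 0.39) rose and foxc1b (-1.61 ± 0.48) fell, also adjusted over the list alone (camera adjusted p = 0.252). The median of 1.41 turned to -1.35 with the stricter filter, under which 7 markers were tested, and to -1.82 with no filter, under which 10 were. Scaled on contractile genes, acta2 (0.40), tagln (0.24) and smtnb (0.33) did not pass, nor did anxa2a (0.25), tbx5a (0.33), mthfd2 (0.79), hmgb3b (0.27) and hmgn3 (0.083) of the other lists, and foxc1b did not in DESeq2 (-1.44). With TMM, contractile genes had a median of 1.18, and endothelial, fibroblast and leukocyte markers had medians of -1.85, -1.90 and -1.92. Of the erythrocyte markers, 1 passed the filter and rose, the carbonic anhydrase gene cahz (1.43 ± 0.42). The 13 in the table summed to 142.4 ± 45.2 and 267.2 ± 163.2 CPM of non-mitochondrial counts (p = 0.114, exact permutation test, n = 4 per group; adjusted p = 0.171). Of 16 neuron and glia markers in the table, 0 passed the filter, and their sums were 76.1 ± 42.7 and 44.5 ± 5.83 CPM (p = 0.314, exact permutation test, n = 4 per group; adjusted p = 0.314).

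**Figure D4:**
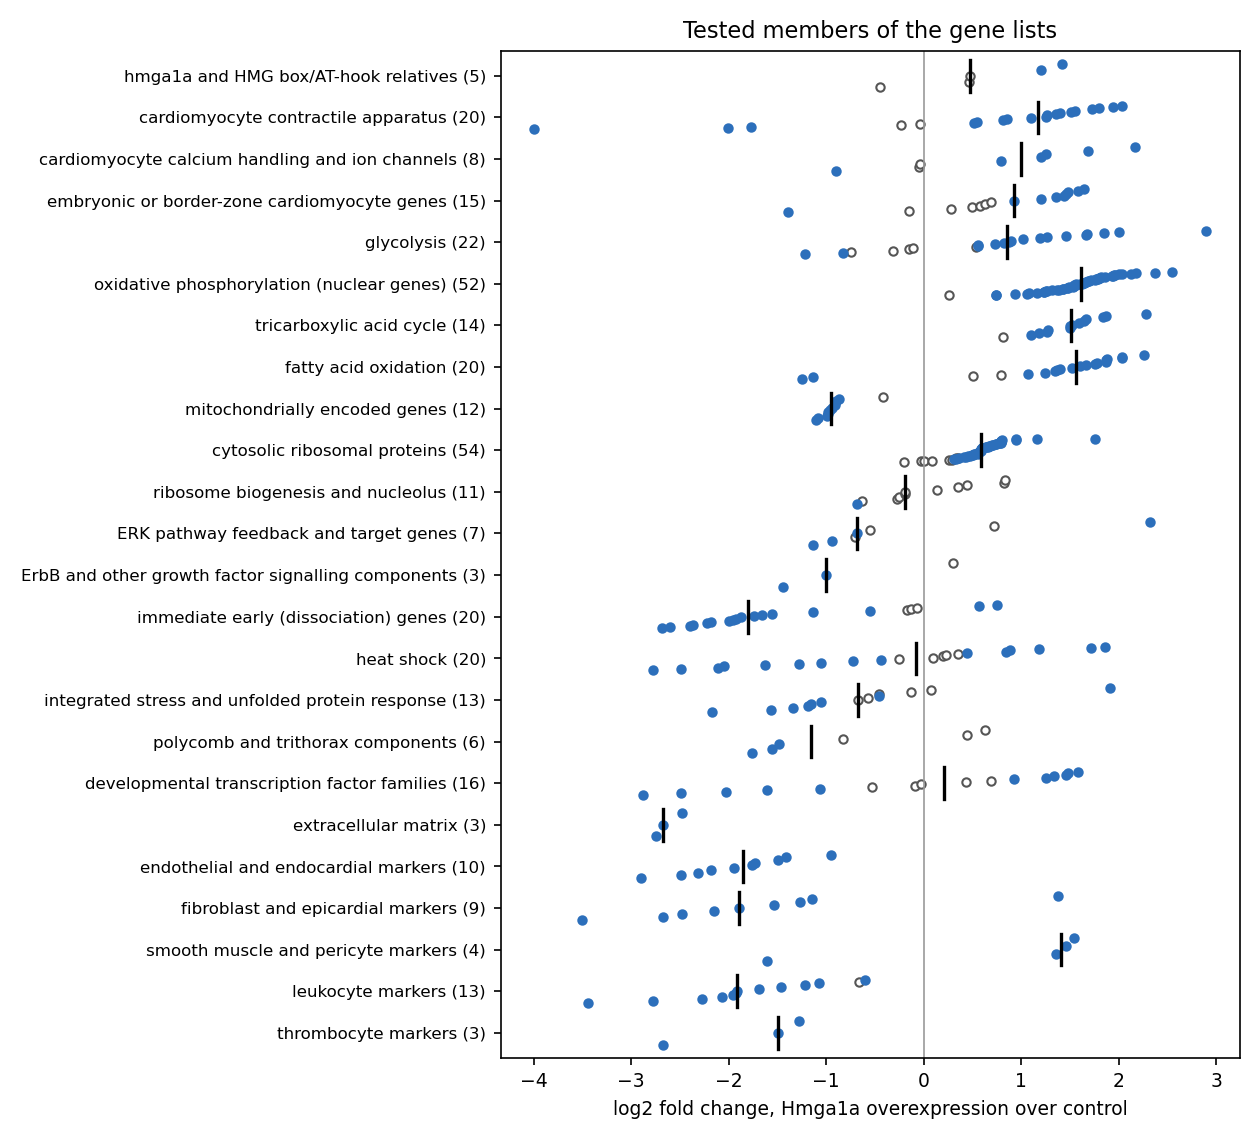
Log2 fold change (overexpression over control) of each tested member of 24 gene lists, with the number tested in parentheses, filled points for adjusted p under 0.05 in edgeR's test and a bar at each list's median. Nuclear oxidative phosphorylation genes lie at a median of 1.61, and endothelial, fibroblast and leukocyte markers between -1.92 and -1.85. Scaling on contractile genes shifted the median of all genes by -1.12 and turned the medians of ribosomal proteins, glycolysis, calcium handling, embryonic cardiomyocyte and HMG genes below 0.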

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

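The tests of explanations given here were chosen after the results were seen.

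In 15 of 226 groups of 4 libraries examined, 1 library lay far from the other 3, where chance gives about 1 in 20. Of these, 10 were in controls and 7 of those were control 2, the shallowest library. There 1 count stands for 30.2 CPM, so its values for pgam2, glrx5, hmgb3b and nkx2.5 rest on few counts. In control 2, pgam2 was at 30.2 CPM (others 3.68 to 5.66), glrx5 at 60.3 (22.1 to 26.8), hmgb3b at 181 (19.8 to 36.8), nkx2.5 at 181 (62.3 to 77.3), atp5po at 965 (600 to 648), ccl34b.4 at 211 (511 to 520) and cd74b at 573 CPM (1200 to 1320). In control 1, myh6 was at 388 CPM (107 to 125) and fn1b at 1100 CPM (520 to 563), and in control 4 mdh1ab was at 136 CPM (90.5 to 91.1). In overexpression 1, hmga1a was at 80.7 CPM (129 to 133) and il6 at 35.6 CPM (3.32 to 6.12). In overexpression 2, ttn.1 was at 412 CPM (276 to 299) and kdm6ba at 294 CPM (215 to 224), and in overexpression 3 hspa4a was at 285 CPM (317 to 323).

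The count of changed genes was compared over splits of the libraries. The real split gave 1490 changed genes, and the highest of the other splits into 4 and 4 libraries gave 1, so that 1 of 35 splits gave as many. That is the smallest share this comparison can give. The other splits mix both groups, so the difference between the groups widens their spread and few calls can arise. The libraries thus differ by group, but the overexpression cannot be told apart from anything else that goes with the group.

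Markers of endothelial cells, fibroblasts and leukocytes fell by medians of -1.85, -1.90 and -1.92 over 10, 9 and 13 genes. Dilution of all markers of a list by one and the same factor is excluded for fibroblast and leukocyte markers, whose members differed beyond their SE (55.4 times the expected squared deviation, 8.54 without anxa2a, which rose, and 5.38; p = 0.0286 each, exact permutation test over libraries). For endothelial markers it stays open (2.45, p = 0.257, exact permutation test), and unequal falls do not exclude a larger cardiomyocyte share, since members that cardiomyocytes also make may fall less and a list can hold markers of several cell types. The largest gap between the medians was 0.0626 (p = 0.993, permutation test with 10000 permutations over genes). Smooth muscle markers lay 3.32 above the others (p = 0.0006, permutation test over genes), but over 4 genes whose median turns negative with the 5 CPM filter. Both p-values treat genes that move together as independent, so they do not measure the spread between libraries. Whether a larger share is the cause or part of it thus cannot be told apart from an effect on these cells. An effect of Hmga1a overexpression on these cells or on their number is untested and stays open, since it goes with the group.

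Mitochondrially encoded genes fell while nuclear genes of the respiratory chain rose. If cardiomyocytes hold more mitochondrial RNA than the other cells, which was not measured here, a larger cardiomyocyte share predicts a rise of both. On that premise the median of -0.95 over 12 genes argues against a larger share as the sole cause of the fall. The median was -0.49 with library totals alone and -1.98 with contractile scaling. The SE of 0.0504 is taken over genes that move together (estimated correlation 0.73), so it does not measure the spread between libraries. Saturation of the identifiers is excluded, since the 4 mitochondrially encoded genes far from saturation had a median of -1.04 (SE 0.164 over genes). A difference in RNA quality or in damage during dissociation was not tested, and an effect of the overexpression stays open.

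The genes ttn.1, ttn.2 and myh6 fell against the median of 1.27 of the 17 other contractile genes. If cardiomyocytes hold more titin RNA than the other cells, which was not measured here, a larger cardiomyocyte share predicts a rise of ttn.1 and ttn.2. On that premise the highest log2 fold change plus 2 SE, -1.42, argues against a larger share as the sole cause of their fall. For myh6, an atrial gene in cells from ventricles, this cannot decide, since the share of atrial cells was not measured. Saturation is excluded, since the highest value in observed identifiers was -1.73 and the genes used at most 786 identifiers. Over the alternatives ttn.2 stayed between -3.10 and -1.59, ttn.1 between -2.89 and -1.37 and myh6 between -5.16 and -3.26. Reads shared between copies and gene length were not tested and stay open, as does an effect of the overexpression.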

How the results depend on the processing

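The 6-library, identifier, saturation and contractile-scaling alternatives were chosen after seeing the data. The cause of the changes given here was not tested, except where fewer genes or libraries were tested. Of 107 named genes, 74 kept direction and call in each alternative in which they were tested, and 89 in each but contractile scaling; with thinned libraries 57 of the 107 were tested. The gene hmga1a, not called, passed in 3 alternatives and was at -0.69 with contractile scaling. With library totals alone 479 genes were lower, hmga1a was at 0.80 and the thrombocyte list at an adjusted p of 0.0504. With the stricter filter 1146 genes of 6175 were higher and hmga1a was at 0.72. With libraries thinned to the smallest, 284 of 505 genes tested changed, 131 higher and 153 lower, and 43 of the 416 genes called before and tested there changed sign. With no filter 1959 of 13443 genes changed, and DESeq2 called 1540. Scaled on contractile genes, 102 genes were higher and 1448 lower, 6.58% higher against 51.0%. The genes atp1b1a (-0.30), rps3a (-0.15), rpl17 (-0.14), rpl14 (-0.29) and rpl32 (-0.32) then changed sign, but none passed as lower (adjusted p from 0.146 to 0.496, edgeR). Over genes tested in both fits, log2 fold changes shifted by a median of 0.368 with library totals alone, 0.235 with no filter, 0.254 with the stricter filter, 0.17 in DESeq2, -0.605 with thinning and -1.12 with contractile scaling. The median of all genes fitted, 0.0084, was then 0.377, -0.138, 0.078, -0.681, 0.027 and -1.11, in that order. In DESeq2 the genes fitted include those of low count that it left without an adjusted p. The share of higher calls with library totals alone was 66.8%.

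With an estimated correlation the adjusted p was 0.272 for the calcium, glycolysis, oxidative phosphorylation, tricarboxylic acid cycle, matrix, endothelial, fibroblast and leukocyte lists, 0.285 for the contractile, fatty acid oxidation, ribosomal protein and immediate early lists, and 0.328 for the embryonic, mitochondrially encoded and thrombocyte lists. Over the authors' 6 libraries the thrombocyte list was at 0.0586. With genes over 50% of the identifiers removed, fewer members were tested: the contractile list (15 of 20, median 1.178 ± 0.447 (SE) against 1.176 ± 0.346) was at 0.0584 and the mitochondrially encoded list (4 of 12, -0.963 ± 0.164 against -0.953 ± 0.0504) at 0.0774. The labels do not say whether the sample numbers pair the libraries. Deviations of same-numbered libraries correlated at 0.0142, -0.0598, -0.026 and 0.00077 across genes, and those of all pairs between -0.065 and 0.070. No sign of pairing was seen, but weak correlations at this depth do not exclude it. With the replicate block 1348 genes changed and the thrombocyte list was at 0.0501. No library correlated best with its own number.

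Leaving out each library in turn, hmga1a ranged from 0.24 to 0.85, the calcium list's adjusted p from 0.0163 to 0.115, that of the stress response list from 0.0311 to 0.128, that of the thrombocyte list from 0.0143 to 0.0633, and the difference in mitochondrial share from -28.1 to -20.5 percentage points (-19.5 to -15.5 without the most abundant RNA). Changed genes ranged from 1300 to 1713. Depth limits genes of low level: 2501 of 21234 genes were tested.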

Other observations

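In the authors' deposited table of terms enriched among raised genes, the large and small subunits of the mitochondrial ribosome, which translates mitochondrially encoded proteins, hold 22 genes (10.6-fold) and 12 genes (11.6-fold). Among lowered genes, the authors' deposited table gives neutrophil chemotaxis (15 genes, 4.54-fold), the semaphorin-plexin pathway (12 genes, 5.2-fold) and artery development (8 genes, 12.6-fold).

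The eGFP entry had counts of 20.05, 8.01, 13.02 and 40.2 in controls 1 to 4 and of 260.1, 320.2, 221.9 and 366.9 in overexpression libraries 1 to 4. Among cell cycle genes, pcna held 62 of the 96 control counts and 108 of the 193 overexpression counts.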
